A study of Mus musculus with 6 samples.

How the data were processed

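RNA was sequenced from mouse CD4 T cells carrying 1 of 2 retroviral vectors, with 3 libraries per vector. Per the labels, naive cells (CD4+ CD44lo CD62L+ CD25neg) were sorted from spleen and lymph node of C57/BL6 mice. They were stimulated for 36 hours on antibodies to CD3 and CD28 at 10 ug/ml, with IL-4 and IFN-gamma blocked, then transduced. After 2 days more, cells with the vectors' GFP marker were sorted. Another label gives the stimulation as 3 days. About 0.5 M sorted cells came from 3 independent biological replicates. TruSeq libraries were made from 2 ug of total RNA and read for 50 cycles, single end, on a HiSeq instrument.

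The deposited table holds 29868 RefSeq transcripts and an FPKM value, which scales reads to transcript length and library size, for each of the 6 libraries. The submitters' processing notes name CASAVA 1.8.2, Cufflinks 2.2, Partek 6.6 and the mouse build mm9, with no role or order. The aligner, the annotation release and any filter are not given in the sources used here, and neither is a strand setting. A value listed at 0 can be a failed estimate. Hmgcs1, a cholesterol synthesis gene, was listed at 0 in all 6 libraries. FPKM is relative to the total, so it shows shares of the RNA pool and not amounts per cell.

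Transcript values were summed per gene. Names came from a RefSeq gene table of assembly GRCm38.p6, used for names only, which matched 29310 transcripts by accession. A further 372 matched by the symbol in the deposited table, 168 kept that symbol, and 18 had none. This gave 22642 genes, 4321 of them with more than 1 transcript. Genes with near-identical copies can have had reads split by the authors' quantification. No genome position is printed, because the builds differ.

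Depth was estimated from the lowest FPKM values of genes with 1 transcript, taken as the value of 1 read. It was 18.4, 39.5 and 17.7 M reads in empty vector replicates 1, 2 and 3, and 44.0, 47.6 and 34.9 M in Blimp-1 replicates 1, 2 and 3. Against empty vector replicate 1, the ratio of these low values lay within 2% of its median for 92.8% to 97.0% of the 79 to 116 genes used per library. At 1 FPKM, a transcript of 1 kb had about 17.7 reads in the shallowest library.

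The 10870 genes at 1 FPKM or more in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, the vector as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2 scale, which understates the change of low genes. Means ± SD are of FPKM. Gene lists, 20 in number, were compared with all other tested genes by camera in limma, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists. List members were also adjusted over the list alone. The 20 lists, the cell type markers and the tests were fixed in advance.

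Both vectors have replicates numbered 1 to 3, and the labels do not say what a number marks. The numbers were tested on the values. Deviations from the vector means correlated at 0.80, 0.81 and 0.70 between same-numbered libraries, and by these deviations each library correlated best with its own number in the other vector. By the log2 values themselves Blimp-1 replicate 3 correlated more with empty vector replicate 1 (0.988) than with replicate 3 (0.984). The numbers were therefore taken to pair the libraries, and a second fit had the replicate number as a block. Unless another fit is named, calls are from the fit without the block, and the blocked value stands beside it where it changes a call.

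On simulated data with 10870 genes, 200 of them changed, the fit without the block recovered 0.4% of 1.5-fold, 39.9% of 2-fold and 93.6% of 4-fold changes, with 0.3 false calls on average. The blocked fit recovered 66.1%, 94.2% and 99.2%, with 10.1 false calls among 183 on average over 10 simulations. The simulated noise was independent with equal variance in all libraries. In the real data the SD of the log2 differences was 0.23, 0.19 and 0.32 in pairs 1, 2 and 3. The recovered shares may therefore not hold for the real data. There Ccl5 (log2 fold change 1.21) and Dapl1 (-1.36) did not pass over all genes with the block (limma adjusted p = 0.142 each).

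Genes were named by a fixed rule with several parts. The first was Prdm1. The next took up to 12 of the largest rises and 12 of the largest falls at 5 FPKM or more among called genes with no overlap between the vectors, leaving out predicted, small RNA and histone genes. Then came a panel of 18 genes of IL-2, IL-10 and STAT signalling and of naive T cells. Each list gave up to 2 members that rose and 2 that fell, and others needed to say what it holds. Markers that changed were named with the most abundant of each cell type. The part on largest changes gave no gene, since the fit without the block called none. Names taken from other fits were chosen after their values were seen.

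Alternatives fixed in advance were pseudocounts of 0.1 and 0.01, no filter, a filter of 5 FPKM, median-ratio rescaling, quantile normalization, limma without the trend or with robust variances, the replicate block, each library left out, an estimated correlation for the lists, an adjusted p threshold of 0.01, and a log2 change of at least 1. Added after seeing the data were the block joined with these choices, a spline correction for transcript length and GC content, the block as a random effect, and each replicate pair left out. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. All 6 per-sample columns matched a library. Lists of actin cytoskeleton and of NF-kB response genes were also made then, leaving out genes whose values had been seen. The values of 1 list member are not reported here.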

Results

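The data were gene expression values from 6 RNA-seq libraries of mouse CD4 T cells activated without polarising cytokines. In 3 libraries the cells carried a MigR1 retrovirus with the cDNA of Prdm1, the gene of the transcriptional repressor Blimp-1, and in 3 they carried the empty vector. Estimated depth was 17.7 to 39.5 M reads with the empty vector and 34.9 to 47.6 M with Blimp-1. Between 10729 and 10850 genes reached 1 FPKM per library. The first principal component, with 52.9% of the variance, set empty vector replicate 3 apart, at 33.7 against -22.7 to 12.6 for the other libraries. Pearson correlations across genes were 0.984 to 0.994 between libraries of the same replicate number, 0.958 to 0.98 between libraries of the same vector, and 0.953 to 0.988 between libraries that shared neither.

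The comparison asks what Blimp-1 changes in activated T cells, and by the series title in particular what it does to target genes of STAT5, the transcription factor of IL-2 signalling. Prdm1 was higher in each Blimp-1 library, at 9.91, 12.8 and 9.45 FPKM in replicates 1 to 3, against 0.996, 2.03 and 1.38 with the empty vector. The means were 10.7 ± 1.83 and 1.47 ± 0.525 FPKM (SD, n = 3 each), a 7.3-fold ratio and a log2 fold change of 2.26 (SE 0.19). The value holds viral and endogenous transcripts together. Igfbp4, which encodes an insulin-like growth factor binding protein and is expressed in naive T cells, was at 220 ± 68.8 FPKM with the empty vector and at 53.8 ± 15 with Blimp-1 (SD, n = 3 each), a ratio of 0.245 and a log2 fold change of -2.00.

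Without the replicate block, limma called 0 genes as higher and 0 as lower. Prdm1 had the smallest adjusted p, 0.0568, and Igfbp4 had 0.559. There were 123 genes at an unadjusted p below 0.05, with 543.5 expected if p-values were uniform. Without empty vector replicate 2, Prdm1 was called (adjusted p = 0.035). With the block, 1 gene rose and 1 fell, Prdm1 (adjusted p = 0.00499) and Igfbp4 (adjusted p = 0.0073), and 2222 genes were at an unadjusted p below 0.05. Over 29 alternatives the adjusted p of Prdm1 ran from 4.6e-11 to 0.427 and that of Igfbp4 from 8.49e-11 to 1. The values of the vectors did not overlap for 249 genes higher and 254 lower with Blimp-1, 4.6% of those tested against 10% by chance. In 3 of 3 pairs 2482 genes were higher and 2476 lower, 45.6% against 25% with independent signs.

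Each replicate pair was left out of the blocked fit after the data had been seen, which leaves 4 libraries and 1 residual degree of freedom. Without pair 1 the fit called 1 gene as higher and 2 as lower, and without pair 2 it called 3 and 2. Without pair 3 it called 508 and 634. The numbers of genes at an unadjusted limma p below 0.05 differed less, at 801, 2206 and 2811 without pairs 1, 2 and 3. The prior degrees of freedom, the weight of the common variance trend, were 5.15, 6.11 and 15.77. Values from the fit without pair 3 are given below for some of the named genes, and it was singled out because of its count.

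**Figure D1:**
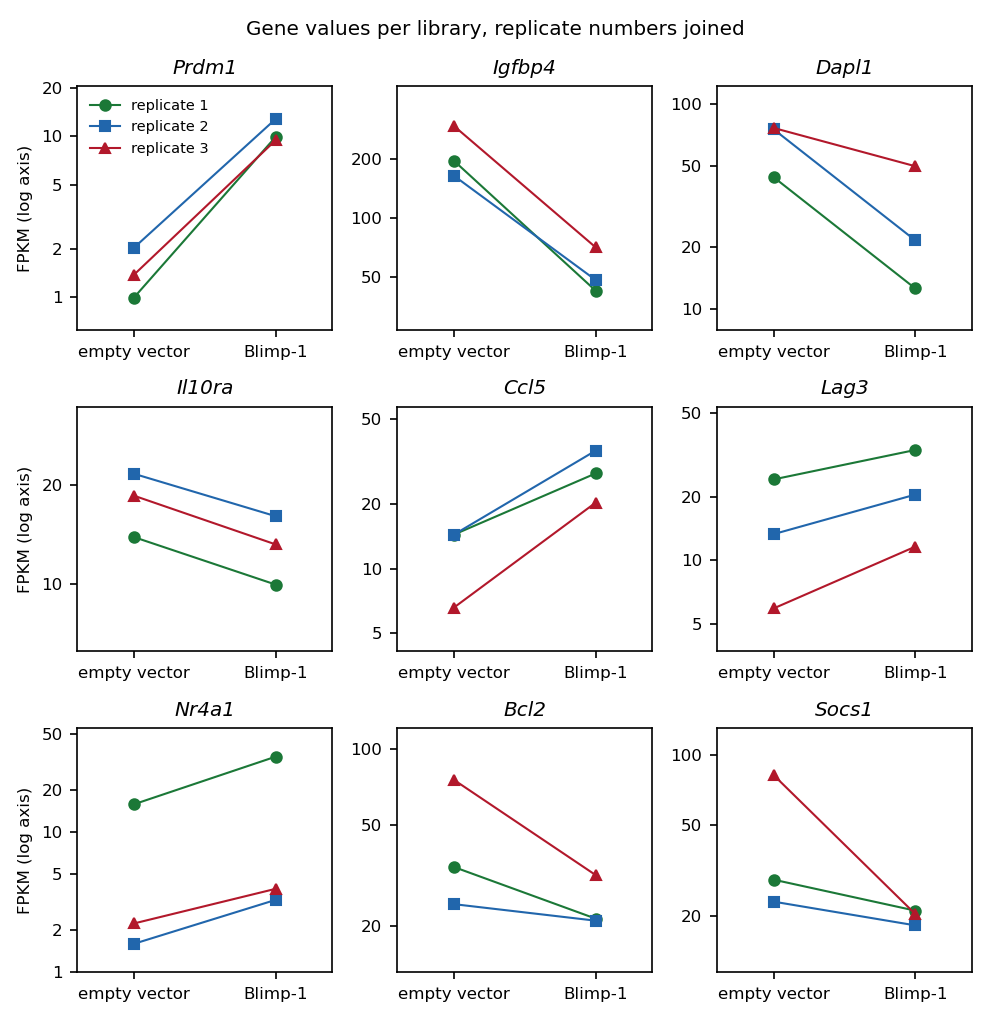
FPKM of 9 genes on log axes in each library, with empty vector on the left, Blimp-1 on the right, and a line joining libraries of the same replicate number. Prdm1 runs from 0.996 to 2.03 with the empty vector and from 9.45 to 12.8 with Blimp-1; Socs1 in empty vector replicate 3 is at 82.2, and its other libraries are at 18.3 to 28.9.

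Several genes of naive and memory precursor cells fell. Of the 16 tested members, 4 fell with the block, adjusted over the list alone, and 12 did not pass. Without the block only Igfbp4 passed over the list alone. Besides Igfbp4 the members that fell with the block were Dapl1 (log2 fold change -1.36, adjusted p = 0.0106), Klf2, a transcription factor of quiescent T cells (-0.49, adjusted p = 0.012), and Id3, an inhibitor of E proteins (-0.33, adjusted p = 0.0274). Dapl1 was at 43.9, 75.1 and 76.2 FPKM with the empty vector and at 12.6, 21.6 and 49.6 with Blimp-1. Over all genes tested only Igfbp4 of this list passed, with the block. Others differed between replicates. Tcf7, a transcription factor of naive and memory cells, had log2 differences of -0.12, -0.35 and 0.73 in replicates 1 to 3, and Il7r, the IL-7 receptor, of 0.00, 0.10 and 1.51. The list as a whole was not called, with a median of 0.05 and camera adjusted p = 0.0818, but it was called as lower without empty vector replicate 3 (median -0.23, adjusted p = 1.03e-06) and without Blimp-1 replicate 2 (median -0.18, adjusted p = 0.00234). These calls were lost with an estimated correlation (adjusted p = 0.534 and 0.613). With the block and both replicate 3 libraries left out, the list fell (median -0.13, adjusted p = 1.35e-05; adjusted p = 0.73 with an estimated correlation), and 7 members fell among all genes tested.

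Camera called 7 lists as higher and 6 as lower without the block, and 0 with an estimated correlation. With the vectors exchanged within 1 pair, the blocked test called 11 or 12 lists, against 11 with the true assignment. With the block and both replicate 3 libraries left out, the STAT5, T follicular helper, trafficking, glycolysis and cholesterol synthesis lists were not called (adjusted p of 0.43, 0.892, 0.38, 0.892 and 0.0706). With an estimated correlation no list was called there (lowest adjusted p = 0.73). That test uses the residual degrees of freedom, 1 in each fit without a pair and 2 in the blocked fit of all libraries. With 1 it could hardly call any list, so its values there do not decide for or against a call. Without pair 1 the interferon call was lost (adjusted p = 0.21), and without pair 2 that of inhibitory receptors (adjusted p = 0.0556). Member calls below are with the block and adjusted over the list alone. Without the block, Ccr6 and Igfbp4 were the members that passed over their lists, and Ccr6 met the filter only through the Blimp-1 libraries.

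STAT5 targets and IL-2 response genes fell as a list by camera, with a median log2 fold change of -0.30 over 20 genes and adjusted p = 0.000917. The list had an adjusted p = 0.599 with an estimated correlation, and 2.37e-07 to 0.747 over 30 alternatives. The list medians were -0.16, 0.04 and -0.74 in replicates 1, 2 and 3. With the block, 1 of the 20 members fell over the list alone, the kinase gene Pim2 (log2 fold change -0.33, adjusted p = 0.0413), none rose and 19 did not pass. The survival gene Bcl2 was at 34.2, 24.4 and 75.5 FPKM with the empty vector and at 21.4, 21 and 31.8 with Blimp-1, with an adjusted p of 0.106 over this list. Socs1, a feedback inhibitor of cytokine signalling, was at 28.9, 23.2 and 82.2 FPKM against 21.2, 18.3 and 20.5 (adjusted p = 0.127), and Cish, another inhibitor of this family, at 48.1, 25.5 and 114 against 49.9, 30.5 and 37.4 (adjusted p = 0.427). Of the 20 members, 14 were higher in empty vector replicate 3 than in both other empty vector libraries, and 17 were above those libraries' mean log2 value, with a median difference of 0.78. Without that library the list median was -0.02 and the call was lost (adjusted p = 0.167). With both replicate 3 libraries left out, Bcl2, Pim2 and Socs1 fell and Bcl2l1 and Cdk6 rose among all genes tested, and the list median was -0.03 (adjusted p = 0.43).

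**Figure D2:**
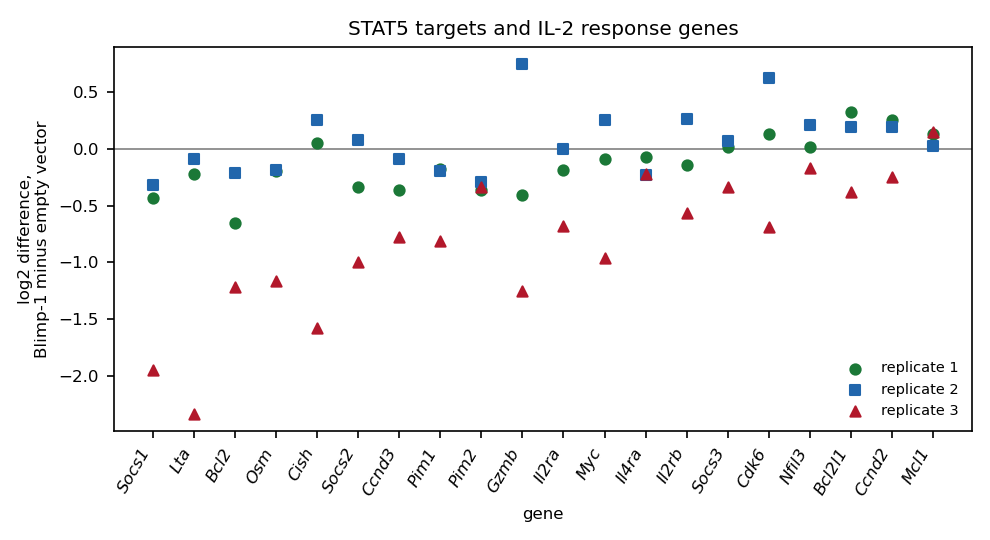
Log2 difference in log2(FPKM + 1), Blimp-1 minus empty vector, for the 20 STAT5 target and IL-2 response genes, 1 point per replicate pair. The replicate 3 differences reach -2.33 for Lta and -1.95 for Socs1, while Pim2 lies at -0.36, -0.29 and -0.34.

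In the panel of IL-2, IL-10 and STAT genes adjusted over the panel alone, Il10ra, the IL-10 receptor chain, fell with the block (log2 fold change -0.44, SE 0.06, adjusted p = 0.00453) and was lower in 3 of 3 pairs. Bcl2 (-0.69, adjusted p = 0.0452) and Id3 (-0.33, adjusted p = 0.0388) also fell by this measure. However, the adjustment counted Prdm1, the gene that the vector carries, as a panel member. Its small p-value eases the threshold for the others. With Prdm1 left out of the adjustment, neither Bcl2 nor Id3 would pass at 0.05, while Il10ra would. Without the block only Prdm1 passed in the panel, and Il10ra had an adjusted p of 0.469. The IL-2 receptor genes did not pass: Il2ra was at 137 ± 51.2 FPKM with the empty vector and 108 ± 16.3 with Blimp-1, Il2rb at 71.7 ± 16 and 64.4 ± 13.2, and Il2rg at 288 ± 31.7 and 283 ± 34.2 (SD, n = 3 each). Log2 fold changes were 0.16 for Stat5a, 0.12 for Stat5b, 0.18 for Stat3, -0.27 for Myc, 0.07 for Ccnd2, 0.43 for Bcl6 and -0.16 for Ccr7, and none passed. Il2 and Il10 stayed below 1 FPKM in each library and were not tested.

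Several lists of effector and inhibitory genes rose. Th1 and cytotoxic genes had a median of 0.21 over 11 genes (camera adjusted p = 0.00853; adjusted p = 0.469 with an estimated correlation). With the block 2 members rose over the list alone, 0 fell and 9 did not pass. Among the latter, Gzmb went from 163 ± 98.1 to 114 ± 6.41 FPKM (SD, n = 3 each). Ifng, Eomes, Prf1 and Gzma did not reach the filter and were not tested. The chemokine gene Ccl5 went from 11.8 ± 4.52 to 27.9 ± 7.59 FPKM (SD, n = 3 each; log2 fold change 1.21, adjusted p = 0.000831) and the chemokine receptor gene Cxcr3 had a log2 fold change of 0.42 (adjusted p = 0.00601). Of the 2 NK cell markers that were tested, both with higher values in 3 of 3 pairs, Klrk1 rose over the markers alone with the block (log2 fold change 0.55, adjusted p = 0.04998) and Klrd1 did not pass (0.72, adjusted p = 0.0585). Over all genes Klrk1 did not pass with the block (limma adjusted p = 0.196). Its values with the empty vector and Blimp-1 were 1.02 and 1.04 FPKM in replicate 1, nearly equal, and 0.158 and 0.903 in replicate 3. Klrd1 was at 12.7, 26.2 and 3.16 FPKM with the empty vector and at 15.1, 30.4 and 12.8 with Blimp-1. IL-10 and inhibitory receptor genes had a median of 0.19 over 8 genes (camera adjusted p = 0.0162; adjusted p = 0.469 with an estimated correlation), and 2 rose, 0 fell and 6 did not pass: Lag3 (log2 fold change 0.63) and Tigit (0.56), both with adjusted p = 0.00408, encode inhibitory receptors. Of the 11 Th17 genes only 4 were tested, and Il17a, Il17f, Il22 and Il23r did not reach the filter. The tested genes had a median of 0.40 (camera adjusted p = 0.0115, or 0.535 with an estimated correlation). Ccr6 and Rora rose from means of 0.652 and 5.03 FPKM with log2 fold changes of 0.65 and 0.29 (adjusted p of 0.00507 and 0.0148). Ccr6 was at 0.405 to 0.927 FPKM with the empty vector and at 1.34 to 1.78 with Blimp-1. It met the filter only through the Blimp-1 libraries, so its rise, and its part in the list result, were favoured by the filter. Trafficking and adhesion genes had a median of 0.16 over 16 genes (adjusted p = 0.019; adjusted p = 0.677 with an estimated correlation), with 3 that rose, Cxcr3 and the integrin genes Itgal and Itgb1, and 13 that did not pass.

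These calls were lost when 1 or another library was left out, which also leaves fewer libraries to test. The Th1 call was lost without empty vector replicate 1 (adjusted p = 0.051) and without Blimp-1 replicate 2 (0.152) or 3 (0.0527). The inhibitory receptor call was lost without empty vector replicate 2 (0.168) or 3 (0.0531) and Blimp-1 replicate 3 (0.0872). The Th17 call was lost without empty vector replicate 3 (0.324) and Blimp-1 replicates 1 (0.479), 2 (0.401) and 3 (0.116). The trafficking call was lost without empty vector replicates 1 (0.343) and 3 (0.441) and Blimp-1 replicates 2 (0.66) and 3 (0.105). The medians shrank in some of these cases and not in others. Without empty vector replicate 3 the Th17 and trafficking medians were 0.07 and 0.01, and without Blimp-1 replicate 2 the Th1 median was 0.06. Without Blimp-1 replicate 3 the Th17, Th1 and inhibitory receptor medians were 0.58, 0.23 and 0.21, no smaller than with all libraries.

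T cell receptor early response genes held members that rose while the list was not called over all 6 libraries. Nr4a1, Nr4a2 and Nr4a3, nuclear receptors induced by antigen receptor signals, and Irf4 rose with the block over the list alone, with log2 fold changes of 0.80, 0.66, 0.51 and 0.33 and adjusted p of 0.00245, 0.00198, 0.00439 and 0.0252. The other 10 of 14 members did not pass, and the list had a median of 0.04 (camera adjusted p = 0.997). With the block and both replicate 3 libraries left out, the list was called as higher (median 0.11, adjusted p = 0.0278; adjusted p = 0.73 with an estimated correlation), with 5 members that rose and 2 that fell among all genes tested. Nr4a1 was far higher in both replicate 1 libraries, at 15.7 and 34.3 FPKM, than in the others, at 1.59 to 3.92. Over the alternatives its log2 fold change ran from -0.18 to 1.65, and that of Nr4a2 from 0.06 to 1.29. Regulatory T cell genes rose as a list without the block (median 0.17 over 10 genes, adjusted p = 0.0134; adjusted p = 0.456 with an estimated correlation) but not with it (adjusted p = 0.0852), and 1 member, Ebi3, a subunit of IL-27 and IL-35, rose over the list alone with the block (0.55, adjusted p = 0.0174). The list's call was lost without empty vector replicate 1 (adjusted p = 0.0757) or 2 (0.338) and without Blimp-1 replicate 3 (0.107). T follicular helper genes had a median of 0.13 over 12 genes (adjusted p = 0.0316; adjusted p = 0.677 with an estimated correlation) and no member that passed. The call was lost without empty vector replicate 3 (median -0.04, adjusted p = 0.649), Blimp-1 replicate 2 (adjusted p = 0.152) or Blimp-1 replicate 3 (adjusted p = 0.116). Th2 genes were not called (median 0.10 over 5 genes, adjusted p = 0.41).

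**Figure D3:**
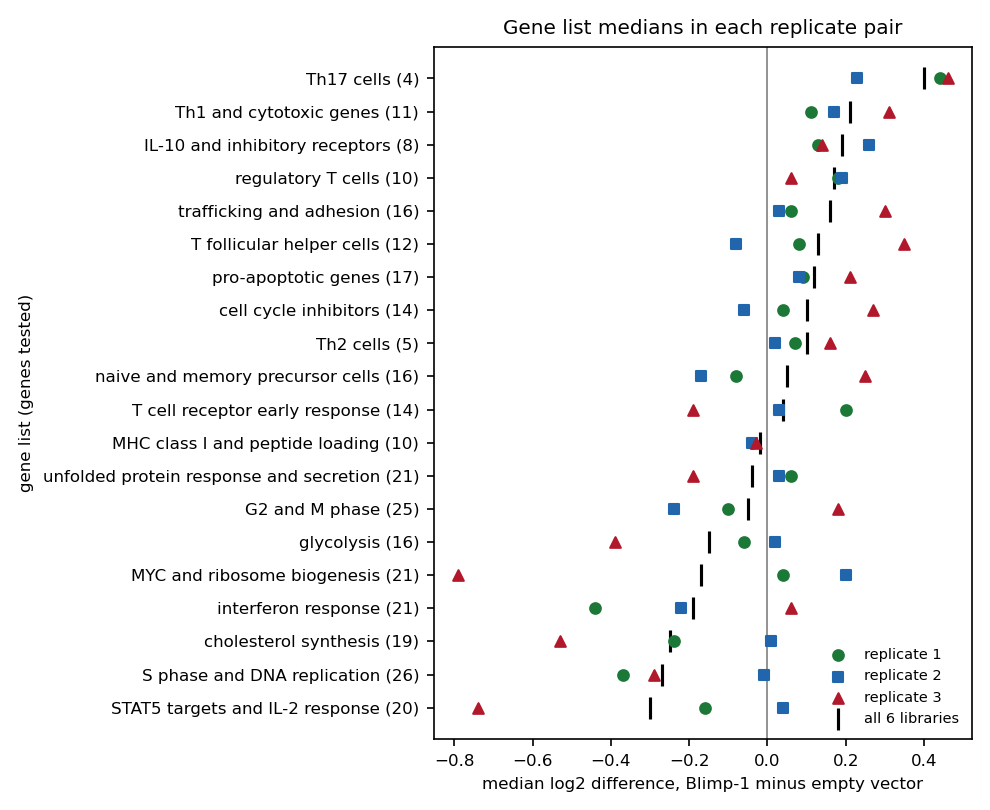
Median log2 difference, Blimp-1 minus empty vector, of the tested genes of each of 20 gene lists, with 1 point per replicate pair and a bar for all 6 libraries. For STAT5 targets the pairs lie at -0.16, 0.04 and -0.74, and for MYC and ribosome biogenesis at 0.04, 0.20 and -0.79.

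S phase and DNA replication genes fell as a list, with a median of -0.27 over 26 genes (camera adjusted p = 0.00118; adjusted p = 0.677 with an estimated correlation). With the block 2 members fell over the list alone, 0 rose and 24 did not pass. These were Ccne1, which encodes cyclin E1 (12.1 ± 4.76 against 8.23 ± 2.37 FPKM, SD, n = 3 each; log2 fold change -0.47), and Tyms, which encodes thymidylate synthase (15.9 ± 3.91 against 12.5 ± 3.54; -0.33), both with adjusted p = 0.0433. List medians were -0.37, -0.01 and -0.29 in replicates 1, 2 and 3, and 14 members were lower in 3 of 3 pairs. Without empty vector replicate 3 the median was 0.04 (adjusted p = 0.569), and without Blimp-1 replicate 2 it was -0.08 (adjusted p = 0.401). With the block and both replicate 3 libraries left out, the list fell (median -0.19, adjusted p = 5.77e-06; adjusted p = 0.73 with an estimated correlation), and 6 members fell among all genes tested. G2 and M phase genes were not called (median -0.05 over 25 genes, adjusted p = 0.41). They were called as lower without empty vector replicate 2 (median -0.3, adjusted p = 0.00116) and without Blimp-1 replicate 3 (-0.35, adjusted p = 1.35e-06), and as higher without Blimp-1 replicate 2 (0.26, adjusted p = 1.11e-05). With an estimated correlation these were not called (adjusted p = 0.559, 0.767 and 0.692). With the block and both replicate 3 libraries left out, they fell (median -0.17, adjusted p = 1.37e-08; adjusted p = 0.73 with an estimated correlation), and 6 members fell among all genes tested, Birc5, Ccnb2, Ccnf, Cdk1, Cenpa and Kif20a.

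Among cell cycle inhibitors, Ccng1 (log2 fold change 0.36, adjusted p = 0.0189) and the antiproliferative gene Btg1 (0.41, adjusted p = 0.0424) rose and Gadd45g (-0.58, adjusted p = 0.0256) fell over the list alone with the block, and 11 of 14 members did not pass. The list was not called (median 0.10, adjusted p = 0.0772), but it was without empty vector replicate 1 (median 0.16, adjusted p = 0.0418) and without Blimp-1 replicate 2 (0.14, adjusted p = 0.0313). With an estimated correlation neither was called (adjusted p = 0.713 and 0.613). With the block it was also called without pair 1 (0.12, adjusted p = 0.0495; adjusted p = 0.825 with an estimated correlation) and pair 2 (0.14, adjusted p = 0.0164; adjusted p = 0.652 with an estimated correlation). Pro-apoptotic genes rose as a list (median 0.12 over 17 genes, adjusted p = 0.0108; adjusted p = 0.456 with an estimated correlation), with 3 members that rose with the block: Pmaip1, which encodes Noxa (0.38, adjusted p = 0.0342), Bmf (0.59, adjusted p = 0.0411) and Apaf1 (0.25, adjusted p = 0.0448). The other 14 did not pass, and the list's call was lost without empty vector replicate 2 (adjusted p = 0.113) or Blimp-1 replicate 3 (adjusted p = 0.116).

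Interferon response genes fell as a list (median -0.19 over 21 genes, adjusted p = 0.0108; adjusted p = 0.677 with an estimated correlation), with medians of -0.44, -0.22 and 0.06 in replicates 1, 2 and 3. Usp18, a negative regulator of interferon signalling, fell with the block over the list alone (13.7 ± 3.99 against 7.76 ± 2.6 FPKM, SD, n = 3 each; log2 fold change -0.76, adjusted p = 0.003), and 20 members did not pass. With both replicate 3 libraries left out, 11 of the 21 fell among all genes tested, and the list had an adjusted p of 1.19e-08, or 0.73 with an estimated correlation. Among them were Irf7 (-0.59, adjusted p = 0.000148), Isg15 (-0.59, adjusted p = 0.000265) and Rtp4 (-0.86, adjusted p = 1.24e-05), whose replicate 3 differences were 0.01, -0.10 and 0.23. The list call was lost without any 1 of empty vector replicates 1 and 2 and Blimp-1 replicates 1 and 3 (adjusted p of 0.0652, 0.625, 0.141 and 0.176).

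Cholesterol synthesis genes (median -0.25 over 19 genes, adjusted p = 0.0134) and glycolysis genes (median -0.15 over 16 genes, adjusted p = 0.00841) fell as lists, each with adjusted p = 0.677 with an estimated correlation and no member that passed. Fdps, of the mevalonate pathway, was at 174, 81.7 and 323 FPKM with the empty vector and 134, 73.1 and 194 with Blimp-1, and the lactate dehydrogenase gene Ldha at 1020, 888 and 1450 against 952, 824 and 954. Without empty vector replicate 3 their medians were 0.05 (adjusted p = 0.517) and -0.04 (adjusted p = 0.649). The cholesterol call was also lost without empty vector replicate 1 (adjusted p = 0.343) or Blimp-1 replicate 2 (adjusted p = 0.766), and the glycolysis call without Blimp-1 replicate 2 (adjusted p = 0.152) or 3 (adjusted p = 0.104). MYC and ribosome biogenesis genes fell without the block (median -0.17 over 21 genes, adjusted p = 0.037; adjusted p = 0.677 with an estimated correlation) but not with it (adjusted p = 0.33), and without both replicate 3 libraries they rose (median 0.14, adjusted p = 0.00541; adjusted p = 0.73 with an estimated correlation). With the block they fell without pair 1 (median -0.24, adjusted p = 0.0497) and without pair 2 (median -0.41, adjusted p = 0.00193), with adjusted p = 0.862 and 0.652 with an estimated correlation. Their call was lost without empty vector replicate 3 (median 0.03, adjusted p = 0.547) and Blimp-1 replicates 1 (adjusted p = 0.0525) and 3 (adjusted p = 0.797). Genes of the unfolded protein response (median -0.04 over 21 genes, adjusted p = 0.888) and of MHC class I presentation (median -0.02 over 10 genes, adjusted p = 0.751) were not called.

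Among the genes called with both replicate 3 libraries left out, those below were picked by the fixed rule for largest changes, after their values were seen. Those that rose included Klrc1, an inhibitory lectin receptor (log2 fold change 0.84, adjusted p = 0.000219), Arrdc4 (0.80, adjusted p = 0.000145), Serpine2 (0.62, adjusted p = 0.00012) and the transcription factor gene Runx2 (0.54, adjusted p = 0.000559). Their differences in replicate 3 were 1.02, 0.98, 0.40 and 0.73. Those that fell included Dapl1 (-1.74, adjusted p = 6.23e-11), Pdlim4 (-1.41, adjusted p = 1.75e-09), Alox5ap, which encodes the activating protein of 5-lipoxygenase (-1.13, adjusted p = 1.23e-06), and Hmgn2, a nucleosome-binding protein gene (-0.69, adjusted p = 6.11e-06). Their differences in replicate 3 were -0.61, -0.33, 0.83 and -0.27.

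T cell genes were abundant in all 6 libraries and none passed over the markers alone: Cd3g, the most abundant, was at 454 to 562 FPKM and Cd4 at 217 to 335. Cd8b1 was at 7.01 to 10.9 FPKM, with Cd8a below 0.17. The most abundant B cell marker was Cd79b (1.04 to 3.57 FPKM), that of macrophages Cd68 (1.08 to 2.06) and of dendritic cells Xcr1 (0.715 to 0.852). For mast cells it was Ms4a2 (0.659 to 1.09), for neutrophils Mpo (up to 0.40) and for fibroblasts Lum (0.0574 to 0.682). That of NK cells was Klrd1 (3.16 to 30.4), and Klrk1 was at 0.158 to 4.87. The other NK cell markers were near 0: Ncr1 was at 0 in all 6 libraries, and Klrb1c, Klre1 and Tyrobp stayed at 0.386 or below. Of the plasma cell genes Xbp1 was the most abundant (31.6 to 56.7 FPKM), and Irf4 rose with the block over its markers alone (limma adjusted p = 0.0144). Of the MHC class II genes, with the block and adjusted over the markers alone, H2-Eb1 (log2 fold change 0.48) and Cd74 (0.58) rose, both with adjusted p = 0.0141, and H2-Ab1, at 49.6 to 97.9 FPKM, fell (-0.20, adjusted p = 0.0449). Cd74 was at 10.7 and 22.9 FPKM in the replicate 2 libraries and at 2.63 to 5.88 in the others. The class II gene H2-Aa (1.78 and 3.53 FPKM) and the B cell marker Cd79b (2.73 and 3.57) were also highest in the replicate 2 libraries. H2-Aa and Ciita, the class II genes that did not reach the filter, stayed at 3.53 and 0.181 FPKM or below. The haemoglobin gene Hba-a1, the only erythroid marker tested, was at 2.01, 2.08 and 18.7 FPKM with the empty vector and 0.663, 0.318 and 2.98 with Blimp-1 (log2 fold change -1.46). It did not pass over all genes with the block (limma adjusted p = 0.142; unadjusted p = 0.00194, or 0.0939 without the block). It was highest in empty vector replicate 3, the library without which 9 of the 13 list calls were lost: STAT5, Th17, T follicular helper, IL-10 and inhibitory receptors, trafficking, S phase, MYC, glycolysis and cholesterol synthesis. Without Blimp-1 replicate 3, where Hba-a1 was at 2.98 FPKM, 10 of the 13 were lost. Hbb-bs, the beta globin gene, was at 0.123 or below.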

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

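The lists, the tests, the leave-outs of 1 library and the first alternatives were chosen before the data were examined; the block joined with another choice, the length and GC correction, the random-effect block, the leave-outs of a replicate pair and those of a library with an estimated correlation were chosen after seeing the data. Where a value moved, the cause was not tested in this section, except that a pair left out means fewer libraries. Tests on the calls without the replicate 3 pair are given further below. Depth limits low genes most, since a 1 kb transcript at 1 FPKM had about 17.7 reads in the shallowest library. Camera could not be run with the random-effect block.

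For Prdm1 the direction held under 29 alternatives, and it passed in 16. Its log2 fold change was 2.26 with median-ratio rescaling (adjusted p = 0.041, in a range of 4.6e-11 to 0.427 over the alternatives) and 2.26 with the replicate block. The blocked value was also 2.26 with the stricter filter, median-ratio rescaling, quantile normalization, robust variances or as a random effect, 2.83 with a pseudocount of 0.1 and 2.91 with 0.01. With the length and GC correction it was 2.23, with or without the block. With 1 library left out it ran from 2.11 to 2.42. Without replicate pairs 1, 2 and 3 it was 2.16, 2.29 and 2.32, and 2.29 without pair 3 with the correction.

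The number of genes that rose, 0 without the block, was 1 with median-ratio rescaling, 1 with the length and GC correction, and 1 with the block alone. It was 1 with the block and either pseudocount, the stricter filter, median-ratio rescaling, quantile normalization, robust variances or the correction, and 2 with the random-effect block. With 1 library left out it was 0 to 1. The number that fell was 1 with the block and in each of these blocked fits but the pseudocount of 0.01, with 2, and the random effect, with 3, and was 0 with each library left out. Without filtering, the blocked fit called 0 and 0, with 2606 genes at an unadjusted p below 0.05 in limma. Without pair 1 the counts were 1 and 2, without pair 2 they were 3 and 2, and without pair 3 they were 508 and 634, or 192 and 220 with the correction.

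The number of lists that rose, 7, was 2 with no filter, 4 with no filter and the block, 3 with the stricter filter and the block, and 0 to 6 with 1 library left out. The number that fell, 6, was 2 to 6 with 1 library left out. With an estimated correlation 0 rose and 0 fell, with or without the block, where that test had 2 and 4 residual degrees of freedom. The replicate block ended the calls of the regulatory T cell and MYC lists and changed no other list's call.

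Reversed values came mostly from the replicate 3 libraries. Without empty vector replicate 3 the medians were -0.04 for T follicular helper genes, 0.04 for S phase, 0.03 for MYC and 0.05 for cholesterol synthesis. Without Blimp-1 replicate 2 they were 0.26 for G2 and M phase and -0.04 for cholesterol synthesis, where the test's direction turned and the median kept its sign. Without replicate pair 3 and with the block, Tcf7 was at -0.23 and the MYC median at 0.14, or 0.13 with the correction as well. There the test's direction also turned for T follicular helper genes (medians 0.03 and 0.04) and T cell receptor genes (0.11 and 0.14), whose medians kept their sign. With 1 library left out the medians ran from -0.04 to 0.29 for T follicular helper genes, -0.51 to 0.04 for S phase, -0.35 to 0.26 for G2 and M phase, -0.31 to 0.03 for MYC and -0.59 to 0.05 for cholesterol synthesis. Other lists that crossed 0 were naive and memory precursor (-0.23 to 0.36), T cell receptor (-0.09 to 0.14), unfolded protein response (-0.09 to 0.04) and MHC class I genes (-0.06 to 0.01). Of 1091 comparisons of a named gene under an alternative, 32 changed sign.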

Other observations

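Tests on depth, on the prior degrees of freedom, on the direction in replicate 3, on the replicate 3 libraries, on Igfbp4 and on other assignments of the gene counts were chosen after the result was seen, and the lists of actin and NF-kB genes were made after looking at single genes. Genes of the actin cytoskeleton were lower with Blimp-1, with a median log2 fold change of -0.12 over 23 genes by camera with the block (p = 8.66e-05 from limma; p = 0.0604 with an estimated correlation). Adjusted over the list alone 5 fell, 0 rose and 18 did not pass: Pfn1, which encodes profilin (log2 fold change -0.49), Cfl1, which encodes cofilin (-0.43), Cotl1 (-0.32), Coro1a (-0.30) and Myl12a (-0.27). Pfn1 was at 609, 733 and 1080 FPKM with the empty vector and at 416, 630 and 653 with Blimp-1. With the length and GC correction the median was -0.05 and 3 members fell, and the list passed with the preset correlation but not with an estimated one (unadjusted p = 0.0614 from camera in limma).

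NF-kB response genes were higher with Blimp-1, with a median of 0.24 over 14 genes by camera with the block (p = 2.57e-05, or 0.15 with an estimated correlation). Adjusted over the list alone 6 rose and 8 did not pass: Relb (log2 fold change 0.47), Bcl3 (0.36), Tnfaip3 (0.34), Nfkb1 (0.27), Birc3 (0.27) and Icam1 (0.27), each with adjusted p = 0.019. Without the replicate 3 pair the median was 0.13 and 6 members rose over the list alone (p = 0.000201 from camera in limma; p = 0.434 with an estimated correlation), and in empty vector replicate 3 the list's median was -0.39 relative to the mean of the other empty vector libraries. Without the block no member of either list passed.

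The first pattern is the 1142 genes called without the replicate 3 pair, where the 2 assignments of the vectors are too few for a share under 0.05: 1 gave as many, with 0 called in the other. If depth were the only cause and its effect were proportional to the log2 depth gap, replicate 2 differences would have a bounded slope on those of replicate 1. The bound is 0.21, the ratio of the depth gaps, but the slope was 0.43 (95% bootstrap interval over genes 0.39 to 0.46). The interval takes genes as independent and holds no spread between replicates. Within that limit, the slope argues against depth as the only cause if the effect is proportional, which was not tested. Blimp-1 was deeper in each pair, by 1.26, 0.27 and 0.98 on the log2 scale, so a part from depth stays open. After the length and GC correction 412 genes were called, 403 of them among the 1142, while over 1107 of these in both fits the median absolute log2 fold change went from 0.33 to 0.31, the median SE from 0.079 to 0.074, and 1105 kept their sign. The calls ended mainly because the prior degrees of freedom fell from 15.77 to 7.65, since with the former value 1072 genes were called after the correction, 857 of them among the 1142, and the part that the trend may account for stays open. Of the genes called after the correction 76.9% went the same way in the left-out pair, against 61% of those not called. This was 87% against 61.9% for genes that rose and 68% against 60% for genes that fell. A response that pair shares is therefore a candidate explanation mainly for the rises and stays open for the falls. Since Blimp-1 was also deeper in that pair, these shares cannot tell a response from a depth effect.

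The second pattern is the lower STAT5 list. Without the replicate 3 pair its median was -0.03, so the list result may rest on that pair. Relative to the other libraries of the same vector, the list was at 0.78 in empty vector replicate 3 and at 0.05 in Blimp-1 replicate 3. Leaving out the pair cannot tell an unusual empty vector library from an effect of the vector in that pair alone. With the block and the length and GC correction the median was -0.25, which argues against that trend as the whole cause. In empty vector replicate 3 the NF-kB genes had a median of -0.39 relative to the mean of the other empty vector libraries, with 0 of 14 above it. This argues against a general NF-kB activation for those genes only, since the list left out genes whose values had been seen. Blimp-1 replicate 3 was also low, at -0.32 relative to the other Blimp-1 libraries. Outside the list, Tnf was at 31.5 FPKM in empty vector replicate 3, against 4.42 and 4.91 in the other empty vector libraries. Lta was at 104 FPKM there, against 23.3 and 20.2. A biological difference of that culture stays open, and Pim2 was lower in 3 of 3 pairs.

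The third pattern is Igfbp4, which stayed at -1.98 with the block and the length and GC correction, against that trend as its cause. A lower share of naive cells is a candidate explanation that cannot be told apart from regulation of the gene: the median of the other 15 naive and memory precursor genes was 0.07, but most of them are also expressed in activated cells. The sort for the vectors' GFP marker, after stimulation, would remove cells that stayed undivided and were not transduced, so only transduced cells that kept such expression are meant.

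Other assignments of the vectors are too few for a share under 0.05. Without the block, 10 of the 10 splits of the 6 libraries called as many genes as the real one, 0, with 1 the highest other, and 1 of 10 called as many lists, 13, with 12 the highest other. A split of empty vector replicates 1 and 3 and Blimp-1 replicate 3 from the rest had 2319 genes at an unadjusted p below 0.05 against 123, a structure of the samples. With the block, exchanging the vectors within pairs gave 4 assignments. Of these, 1 called as many genes as the real 2, with 0 the highest other, and 1 had as many at an unadjusted p below 0.05 as the real 2222, with 347 the highest other. All 4 called as many lists as the real 11, with 12 the highest other.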
